A study of Homo sapiens with 15 samples.

How the data were processed

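RNA from 15 libraries of cultured human cells was analysed: A375 melanoma cells, primary dermal fibroblasts (PF) and primary epidermal melanocytes (PM), the last 2 with and without treatment, 3 libraries in each of 5 groups. Per the labels' protocols, A375 was switched to serum-free DMEM for 72 h, the medium was centrifuged and ultrafiltered through 100 kDa filters, and PF and PM were incubated with it for 72 h. Fibroblasts and melanocytes were otherwise grown in their own supplemented media, per the same protocols, and the controls are labelled only as having had no treatment. Change of medium is therefore confounded with conditioning by A375. RNA was column-purified and poly(A)-selected before library construction, per the labels' protocols. Endothelial cells named in the labels were not analysed here.

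The values used were counts per gene, deposited as 1 matrix of 60609 genes by 15 libraries. Per the submitters' processing notes it was made with DRAGEN on GRCh38. Software version, annotation release, strand setting, treatment of shared reads and filters are not given in the sources used here. All values were whole numbers. Library totals were 21193665 to 21903070 counts, a spread of 3.3%, and no source used here says whether reads were subsampled to equal depth. Genes detected per library numbered 21254 to 23571, and mitochondrially encoded genes took 3.23% to 7.28% of the counts. At 3 counts in a library the floor was 0.137 to 0.142 CPM, counts scaled to the library total. All columns mapped to labels. Gene IDs were matched without version to GENCODE 29 (58502 of the genes, 96.5%), used for locations only. Of the genes, 27500 had no count in any library, 1358 shared a symbol with another gene, and 14 had symbols turned into dates.

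Differential expression was tested on counts with edgeR 4.0.16 in R 4.3.3: trimmed mean normalization, the package's expression filter with the groups of each fit, quasi-likelihood fits with robust dispersion, and Benjamini-Hochberg adjusted p under 0.05. Treated and control libraries were compared within PF (15116 genes) and within PM (15671 genes), 6 libraries each. The difference between the effects was tested as an interaction over 12 libraries (16645 genes), and A375 was compared with PM_control (16771 genes). The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. Intervals and floors for genes with 0 to 3 counts in a group cover counting error only. For 27 fixed gene lists with 496 entries in all, camera in limma 3.58.1 was run with its preset correlation of 0.01 on lists with at least 5 tested members, adjusted over lists, and again with an estimated correlation, and fry was run for description. Members were also adjusted over each list alone. Lists, comparisons, tests, the choice of named genes and all alternatives but those named below as added later were set before the data were examined.

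Named genes were chosen by rule. For PF and PM these were the 8 largest rises and the 8 largest falls among genes that passed, with at least 10 CPM in the higher group and all 3 treated libraries on one side of all 3 controls. For the other 2 comparisons they were the 6 largest each way. From each list came up to 4 members with the lowest adjusted p or, where none passed, the most abundant member, and PRAME, MITF, SOX10, MKI67, COL1A1, ACTA2, IL6, CXCL8 and MMP1 were named in each comparison. Genes without a symbol were not named, and 558 genes on the Y chromosome or of X inactivation were tested but not named. Values of some single list members are not reported here.

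Similarity to A375 was the Pearson correlation of each library's log2 CPM (prior count 2) with the mean A375 profile, compared by exact permutation of 10 splits, where 0.1 is the smallest possible p. Transcripts restricted to A375 had at least 20 CPM in each A375 library and under 0.5 CPM in each control library of the cell type. The A375 share of each treated melanocyte library was the median over those genes of its level minus the control mean, as percent of the A375 mean, and it was 11.65%, 0.0973% and 0.2508%.

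Equal replicate numbers were checked as possible pairs by correlating the deviations of treated and of control libraries from their group means across genes. The same-number r was 0.25, 0.17 and 0.19 in PF, 0.34, 0.13 and 0.27 in PM, and 0.22, 0.15 and 0.10 between A375 and PM_control. By these data every pair of PF and of PM was over 0.1, which pairs those libraries by number. The labels name no shared culture or day, and the main analysis had no replicate block and a fit with the block was an alternative, with 3792 genes called in PF and 3816 in PM. Between libraries of a group, the chi-square per gene was 30.53 to 102 for pairs with replicate 1 and 2.517 to 11.49 between replicates 2 and 3.

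Alternatives were DESeq2 size factors, no low-count filter, DESeq2 1.42.0, the replicate block, all 15 libraries in 1 fit, mitochondrially encoded genes left out, a fold threshold and each library left out in turn. Leaving out replicate 1 of every group and subtracting the A375 share from treated melanocytes were added after the data were seen, as were leaving out single treated libraries for the restricted transcripts and sign flips within pairs for similarity. The tests were also tried on simulated data of the same size. There the share of genes recovered at a 2-fold and a 4-fold change was 43.3% and 84.8% in PF, 56.7% and 84.8% in PM, 29.9% and 59.1% for the difference, and 20.9% and 68.2% for A375 against PM_control. Of the calls made there, 7 of 110, 10 of 125, 4 of 72 and 4 of 70 were false. Plots were made with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.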

Results

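RNA was measured by poly(A)-selected sequencing in 15 libraries of human cells, 3 in each of 5 groups. A375, a human melanoma cell line labelled PRAME +/+, was the source of the treatment. Serum-free medium conditioned by A375 for 72 h was cleared by centrifugation and passed over 100 kDa filters, a step that retains large particles such as extracellular vesicles, although the labels do not say which fraction was applied. Primary dermal fibroblasts (PF) and primary epidermal melanocytes (PM) were incubated with that material for 72 h (groups PF_treated and PM_treated) or were labelled as untreated (PF_control and PM_control). The stated purpose was to learn how material shed by melanoma cells alters neighbouring benign cells. The library totals were 21337055 to 21595425 counts in A375, 21720858 to 21903070 in PF_control, 21265516 to 21888985 in PF_treated, 21193665 to 21625252 in PM_control and 21248765 to 21626495 in PM_treated. At these totals 3 counts in a library correspond to 0.137 to 0.142 CPM, counts scaled to the library total in the usual way. Levels below are CPM as mean ± SD of 3 libraries, and log2 fold changes carry their SE. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

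The first question was what changed in fibroblasts incubated with the A375 material. A change of medium cannot be told apart from conditioning by A375, so no change below in PF or PM can be credited to either alone. The largest rises among named genes in PF_treated included cytokine and chemokine genes. CSF3, which encodes granulocyte colony-stimulating factor, rose from 0.518 ± 0.411 to 334.7 ± 47.9 CPM (log2 fold change +9.32 ± 0.44, adjusted p = 8.77e-05). CXCL5, a neutrophil chemokine, rose from 14.5 ± 8.07 to 3834 ± 486 CPM (+8.04 ± 0.56, adjusted p = 0.000305). HAS1, a hyaluronan synthase, rose from 0.901 ± 0.374 to 122.3 ± 14.4 CPM (+7.08 ± 0.28, adjusted p = 5.07e-05). The lipid-droplet gene CIDEC fell from 70.3 ± 49.6 to 0.588 ± 0.327 CPM (-6.88 ± 0.67, adjusted p = 0.000989). ADH1B, an alcohol dehydrogenase, fell from 606.1 ± 517 to 5.28 ± 4.46 CPM (-6.81 ± 1.02, adjusted p = 0.00466). Each of these changes had all 3 treated libraries on one side of all 3 controls (n = 3 per group). In GRCh38 with GENCODE 29 annotation, CSF3 is a protein-coding gene on chromosome 17 from 40015361 to 40017813 on the + strand. CXCL5 lies on chromosome 4 from 73995642 to 73998779 on the - strand, HAS1 lies on chromosome 19 from 51713112 to 51723994 on the - strand, and ADH1B on chromosome 4 from 99304964 to 99352760 on the - strand.

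The other large rises in fibroblasts were CXCL6 (+6.17 ± 0.52), the acute-phase gene SAA1 (+6.14 ± 0.27), CXCL3 (+5.55 ± 0.65), the transcription factor gene POU2F2 (+5.29 ± 0.38) and HEPHL1, a relative of the copper ferroxidase hephaestin. HEPHL1 had 3 counts in all controls together, which gives a ratio of 378.5 with a 95% counting interval of 129.2 to 1838. The other large falls were the galactosyltransferase gene B3GALT2 (-7.64 ± 0.73), the water channel gene AQP3 (-6.41 ± 1.29), and the imprinted long non-coding RNA H19 (-6.07 ± 0.29). Next came the small proteoglycan gene ASPN (-5.76 ± 0.20), the smooth muscle actin-binding gene LMOD1 (-5.62 ± 0.57) and the complement gene C7 (-5.51 ± 0.47). Among genes chosen in advance for every comparison, CXCL8 (+4.19 ± 0.78, adjusted p = 0.00962), MMP1 (+2.11 ± 0.26, adjusted p = 0.00234) and the proliferation marker MKI67 (+1.30 ± 0.36, adjusted p = 0.0356) rose, and ACTA2, the smooth muscle actin of myofibroblasts, fell (-0.68 ± 0.14, adjusted p = 0.0152). COL1A1 (-0.18 ± 0.20, adjusted p = 0.532) and IL6 (+1.18 ± 0.49, adjusted p = 0.117) did not pass. IL6 did with DESeq2 (+1.15, 0.0492), without PF_control replicate 1 (+0.72, 0.00196) and without replicate 1 in both groups (+0.71, 2.47e-08). MITF, at 7.54 ± 0.611 CPM in controls, fell by 1.70 on the log2 scale (SE 0.19, adjusted p = 0.00158). PRAME and SOX10 were too low in fibroblasts to be tested. The calls of CXCL8, AQP3, MKI67 and ACTA2 were lost in some alternatives. For the last 3, leaving out single libraries gave adjusted p of up to 0.0626, 0.0927 and 0.0625, no low-count filter gave 0.0811 for CXCL8, 0.0909 for AQP3 and 0.1485 for MKI67, and a fit of all 15 libraries gave 0.134 for ACTA2. Over single libraries left out AQP3 ran from -6.87 to -4.43 and MKI67 from +0.73 to +1.53. Without replicate 1 in both groups AQP3 was at -4.27, ADH1B at -5.34, CIDEC at -5.78 and MKI67 at +0.85.

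In fibroblasts, inflammatory, matrix protease and cell cycle lists passed upward. Of 20 tested members of the list of inflammatory cytokines and NF-kB targets, 13 rose and 7 did not pass (13 adjusted over the list alone). Their median log2 fold change was +3.07, or +3.04 with CSF2, which had no count in controls, set to its bound, and examples were CSF3, CXCL5, CXCL6 and IL1B (+5.20 ± 0.41). The list passed (adjusted p = 1.60e-15, camera) with adjusted p = 0.354 with an estimated correlation. Of 18 members of the TGF-beta and myofibroblast list, 9 rose, 4 fell and 5 did not pass (17 adjusted over the list alone), and the list passed upward (adjusted p = 0.000365, and adjusted p = 0.281 with an estimated correlation). LTBP2 rose by +3.14 ± 0.14, the cytokine gene IL11 by +3.77 ± 0.23 and FAP, a marker of activated fibroblasts, by +1.58 ± 0.12. The contractile genes TAGLN (-2.08 ± 0.10), MYL9 (-0.67) and ACTA2 fell together with TGFB2 (-1.77). Of 16 matrix proteases and inhibitors, 8 rose, 1 fell and 7 did not pass (9 adjusted over the list alone). They included rises of MMP3 (+4.96 ± 0.55), the gelatinase gene MMP2 (+2.22 ± 0.13) and the membrane protease gene MMP14 (+1.46 ± 0.11) and a fall of the inhibitor gene TIMP3 (-2.04). That list passed upward (adjusted p = 6.49e-06, and adjusted p = 0.529 with an estimated correlation). Members named because they made up a count of 5 or fewer were chosen after their values were seen, here and below.

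Of 25 cell cycle genes, 21 rose and 4 (MCM5, FOXM1, PCNA and TYMS) did not pass (25 adjusted over the list alone), with a median of +1.17. RRM2, a ribonucleotide reductase subunit, rose by +1.75 ± 0.28, and the mitotic kinase genes AURKB by +1.59 ± 0.28 and PLK1 by +1.42 ± 0.22. The list passed upward (adjusted p = 1.74e-09, and adjusted p = 0.529 with an estimated correlation). Of 17 p53 targets and cell cycle inhibitors, 5 fell and 12 did not pass (5 adjusted over the list alone). The fallen genes were BTG2 (-2.42 ± 0.34), CDKN2B (-1.63 ± 0.21), TP53INP1 (-1.07 ± 0.20), CDKN1A (-0.92 ± 0.13) and ZMAT3 (-0.66), and the list passed downward (adjusted p = 0.0197, and adjusted p = 0.529 with an estimated correlation). Of 16 genes of endoplasmic reticulum chaperones and the unfolded protein response, 7 rose and 9 did not pass (9 adjusted over the list alone), among them PDIA4 (+1.07 ± 0.10), HYOU1 (+1.07 ± 0.12) and MANF (+1.01 ± 0.12), with adjusted p = 0.0014, and adjusted p = 0.529 with an estimated correlation. Of 18 MAPK pathway output genes, 7 rose, 2 fell and 9 did not pass (10 adjusted over the list alone). IER3 was at +3.19 ± 0.10 and the growth factor gene HBEGF at +2.06 ± 0.36, against falls of SPRY1 (-1.83 ± 0.20) and EPHA2 (-1.61 ± 0.22). This list passed upward (adjusted p = 0.00469, and adjusted p = 0.546 with an estimated correlation), and without PF_control replicate 1 it did not (adjusted p = 0.0567).

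Interferon-stimulated genes fell in fibroblasts. Of 23 members, 21 fell and 2 did not pass (22 adjusted over the list alone), with a median of -1.87 (adjusted p = 3.87e-14, and adjusted p = 0.529 with an estimated correlation). IFIT1, an antiviral RNA-binding protein gene on chromosome 10 from 89392546 to 89406486 (+ strand), fell from 173.1 ± 21.92 to 15.9 ± 6.97 CPM (-3.42 ± 0.37). Also IFIT3 (-3.27 ± 0.41), XAF1 (-1.87 ± 0.21) and USP18 (-1.38 ± 0.17) fell. Of 17 genes of MHC class I presentation, 7 fell, 1 rose (PDIA3, +0.63) and 9 did not pass (10 adjusted over the list alone). The immunoproteasome gene PSMB9 (-1.28 ± 0.16), the peptide transporter gene TAP1 (-1.04 ± 0.16) and HLA-E (-0.92 ± 0.11) were among those that fell (adjusted p = 0.005, and adjusted p = 0.529 with an estimated correlation). Of 16 FOXO and growth factor withdrawal genes, 5 fell, 1 rose (FOXO3, +0.38) and 10 did not pass (9 adjusted over the list alone). Values were -1.71 ± 0.24 for CITED2, and for the thioredoxin inhibitor gene TXNIP -1.36 ± 0.10, PIK3IP1 -1.21 ± 0.14 and KLF9 -0.95 ± 0.12 (list adjusted p = 0.00303, and adjusted p = 0.281 with an estimated correlation). The ATF4 amino acid response list (5 fell, 2 rose and 14 did not pass of 21, and 8 adjusted over the list alone) passed downward (adjusted p = 0.031, and adjusted p = 0.745 with an estimated correlation). The cystine transporter gene SLC7A11 was at -2.64 ± 0.44 and ATF3 at -1.54 ± 0.29, against rises of VLDLR (+1.40) and CEBPB (+0.80 ± 0.10). That response list did not pass without PF_control replicate 2 (0.108), PF_control replicate 3 (0.108) or PF_treated replicate 1 (0.0637). Fatty acid synthesis (2 fell and 10 did not pass of 12, SREBF1 at -0.91 ± 0.13 and ELOVL5 at -0.40 ± 0.12, 1 adjusted over the list alone) passed downward (adjusted p = 0.0357, and adjusted p = 0.745 with an estimated correlation). The list did not without PF_control replicate 1 (0.224), PF_treated replicate 2 (0.0974) or PF_treated replicate 3 (0.112). Genes of vesicle biogenesis and tetraspanins (7 fell, 1 rose and 8 did not pass of 16, with 8 adjusted over the list alone) also passed downward (adjusted p = 0.0351, and adjusted p = 0.529 with an estimated correlation). Examples were CD9 at -1.73 ± 0.35, ANXA5 at -0.95 ± 0.14 and CD81 at -0.80 ± 0.13 against CD82 at +0.76. The vesicle list did not pass without PF_control replicate 2 (0.0799), PF_control replicate 3 (0.0618) or PF_treated replicate 1 (0.0671). Calls of single genes ended too. ELOVL5 passed in 1 of 6 fits with a library left out (adjusted p up to 0.143), and CD9, at -1.11 without replicate 1 in both groups, did not pass without PF_treated replicate 1 or 3 (up to 0.0581). SLC7A11 was lost with no low-count filter (0.0533) and TXNIP in the fit of all 15 libraries (0.13).

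Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3871 of 15116 tested genes in fibroblasts, 1913 higher and 1958 lower, of which 1739 changed at least 2-fold. All 3 treated libraries lay on one side of all 3 controls for 47.4% of tested genes, where chance gives 10%. Of 24 lists tested with camera, 13 passed, 6 upward and 7 downward, none (0) held with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry called 13. Replicate 1 stood apart from replicates 2 and 3 in every group, with a chi-square per gene of 30.5 to 72.7 against replicate 1 and 2.52 to 5.05 between replicates 2 and 3 in the fibroblast groups. Without replicate 1 in both groups 7759 genes were called. That fit was chosen after the data were seen and keeps only replicates 2 and 3, the closest libraries. Its calls and low adjusted p, here and below, are therefore weak support. Without PF_control replicate 2 the count was 2455, without PF_control replicate 3 it was 2565, and without PF_treated replicate 1, 2 or 3 it was 2465, 2144 or 1818.

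**Figure D1:**
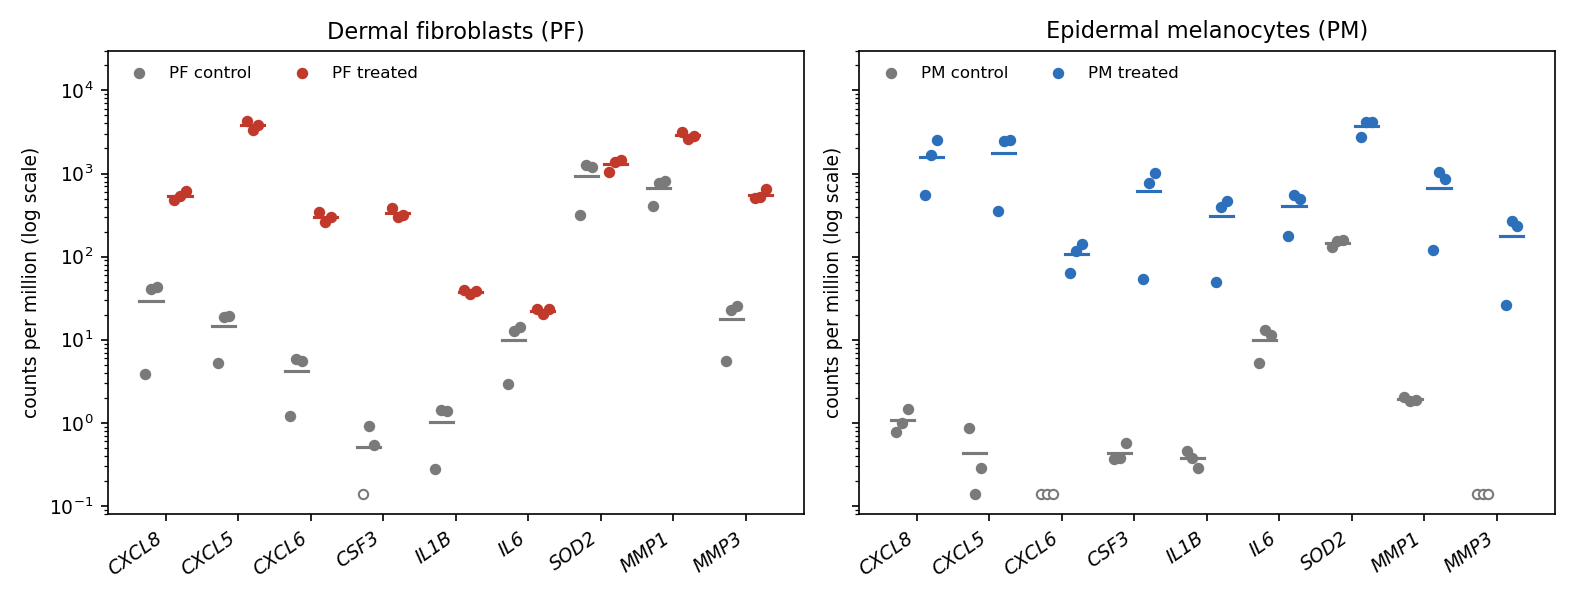
Levels of 9 inflammatory and protease genes in CPM on a log axis, with fibroblasts (PF) in the left panel and melanocytes (PM) in the right panel; each dot is 1 library, bars are means of 3 libraries, and open dots are libraries under 0.14 CPM drawn at that level. Treated libraries lay above controls for each gene except SOD2 in PF, where CSF3 rose from 0.518 to 334.7 CPM in PF and CXCL8 from 1.08 to 1584 CPM in PM.

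The second question was what changed in melanocytes incubated with the same material, where change of medium is confounded likewise. All 20 tested genes of the inflammatory list rose, and 15 of 19 pigmentation genes fell. CXCL8, the gene of the neutrophil chemokine interleukin-8, rose from 1.08 ± 0.348 to 1584 ± 986 CPM (+10.59 ± 0.78, adjusted p = 0.00202), and CXCL5 from 0.434 ± 0.392 to 1766 ± 1221 CPM (+12.05 ± 1.16, adjusted p = 0.00338). CSF3 rose by +10.52 ± 1.38 and IL1B by +9.73 ± 1.13. The cytokine gene IL6 rose from 9.89 ± 4.17 to 408.0 ± 202 CPM (+5.45 ± 0.58, adjusted p = 0.00403) and the collagenase gene MMP1 from 1.92 ± 0.106 to 673.7 ± 487 CPM (+8.54 ± 0.95, adjusted p = 0.00462). MITF, the transcription factor that controls melanocyte identity, fell from 181.5 ± 37.3 to 53.8 ± 4.64 CPM (-1.69 ± 0.15, adjusted p = 0.00263). SLC45A2, a melanosomal transporter gene, fell from 63.6 ± 12.5 to 12.1 ± 0.87 CPM (-2.33 ± 0.15, adjusted p = 0.00157). CXCL8 lies on chromosome 4 from 73740506 to 73743716 (+ strand), MMP1 on chromosome 11 from 102789920 to 102798160 (- strand), MITF on chromosome 3 from 69739435 to 69968337 (+ strand) and SLC45A2 on chromosome 5 from 33944616 to 33984730 (- strand), all protein-coding.

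A measured fact accompanies every melanocyte group. PM_treated replicate 1 held transcripts restricted to A375 at a median of 11.7% of their A375 level, against 0.183% and 0.348% in PM_treated replicates 2 and 3. In the same library CXCL8, CXCL5 and CSF3 were lowest of the 3 treated libraries, as the plot of inflammatory genes shows. With an A375 share subtracted from the treated libraries 2335 genes were called in place of 2344, and 2067 of them were shared.

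Among the largest rises in melanocytes, MMP3, a stromelysin, had no count in controls and 177.5 ± 132 CPM in treated cells, at least 1265-fold higher against 3 counts per library. ACKR3, a scavenging chemokine receptor gene, was likewise at least 113.7-fold higher. CXCL6 had 1 control count and a ratio of 6950 (95% counting interval 1247 to 274500), and HSD11B1, whose enzyme regenerates cortisol, had 1 control count and a ratio of 3806 (682.6 to 150400). Among genes of at least 10 CPM whose treated and control libraries did not overlap, the largest falls were the oxytocin receptor gene OXTR (67.0 ± 8.86 to 2.42 ± 1.19 CPM, -4.73 ± 0.30), the integrin gene ITGB4 (-3.82 ± 0.49), the metalloreductase gene STEAP4 (-3.62 ± 0.52), and the phospholipase gene PLA1A (-3.60 ± 0.42). Next came PTPRQ (-3.53 ± 0.38), the imprinted gene MEST (-3.41 ± 0.56), the urea transporter gene SLC14A1 (-3.41 ± 0.72) and PLEKHA6 (-3.40 ± 0.39). ACTA2 fell by 0.63 on the log2 scale (SE 0.14, adjusted p = 0.0285), and SOX10 (-0.76 ± 0.26, adjusted p = 0.0962), MKI67 (+0.62 ± 0.54, adjusted p = 0.466) and COL1A1 (-0.56 ± 0.74, adjusted p = 0.639) did not pass. With the replicate block MKI67 (0.0305) and COL1A1 (0.0354) did. However, MKI67 was at -0.05 without PM_treated replicate 1 (adjusted p = 0.955) and +0.38 with the A375 share subtracted, and COL1A1 ran from -1.75 without PM_treated replicate 1 to +0.14 without PM_control replicate 1. COL1A1 also passed without replicate 1 in both groups (0.000116). SOX10, at 1323 CPM in A375, passed with DESeq2 (0.0251), without PM_control replicate 1 (0.00704) and without replicate 1 in both groups (0.000243), and was at -1.12 (0.082) with the A375 share subtracted. PRAME was not tested and had 25.6, 0.370 and 0.235 CPM in the treated libraries 1, 2 and 3 and no count in controls. The calls of MMP3, HSD11B1, ACKR3, STEAP4, MEST, SLC14A1 and ACTA2 were lost in some alternatives, with adjusted p of up to 0.209, 0.0577, 0.342, 0.0519, 0.062, 0.132 and 0.256. Without PM_treated replicate 1 STEAP4, MEST and SLC14A1 were at -4.30, -4.51 and -4.70. Of 95 named genes that passed in melanocytes, 41 passed with each library left out in turn, 92 with the replicate block and 95 without replicate 1. The last fit was chosen after the data were seen and keeps replicates 2 and 3, the closest libraries of each group. Its count was thus near fixed in advance and is no sign of stability.

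All 20 tested members of the list of inflammatory cytokines and NF-kB targets rose in melanocytes (20 adjusted over the list alone), with a median of +6.88, or +6.54 with IL1A, which had no count in controls, set to its bound. Examples were CCL20, a lymphocyte chemokine gene (+6.69 ± 0.19), the mitochondrial superoxide dismutase gene SOD2 (+4.73 ± 0.23) and LIF (+3.94 ± 0.18). The list passed upward (adjusted p = 4.93e-94, and adjusted p = 0.0853 with an estimated correlation), and all 20 rose also without PM_treated replicate 1. With the A375 share subtracted 19 members were tested, and all 19 rose. Of 19 members of the pigmentation and melanocyte lineage list, 15 fell and 4 (SOX10, PAX3, EDNRB and MC1R) did not pass (18 adjusted over the list alone), with a median of -1.56 (adjusted p = 3.93e-22, and adjusted p = 0.386 with an estimated correlation). TRPM1, a melanocyte ion channel gene, fell by 2.81 on the log2 scale (SE 0.31), and SLC24A5, a melanosomal cation exchanger gene, by 1.73 (SE 0.17). A375 itself had no count of TYR, MLANA or TRPM1. Without PM_treated replicate 1, 12 of the 19 fell, with a median of -1.35, and with the A375 share subtracted 14 fell, with a median of -1.48.

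**Figure D2:**
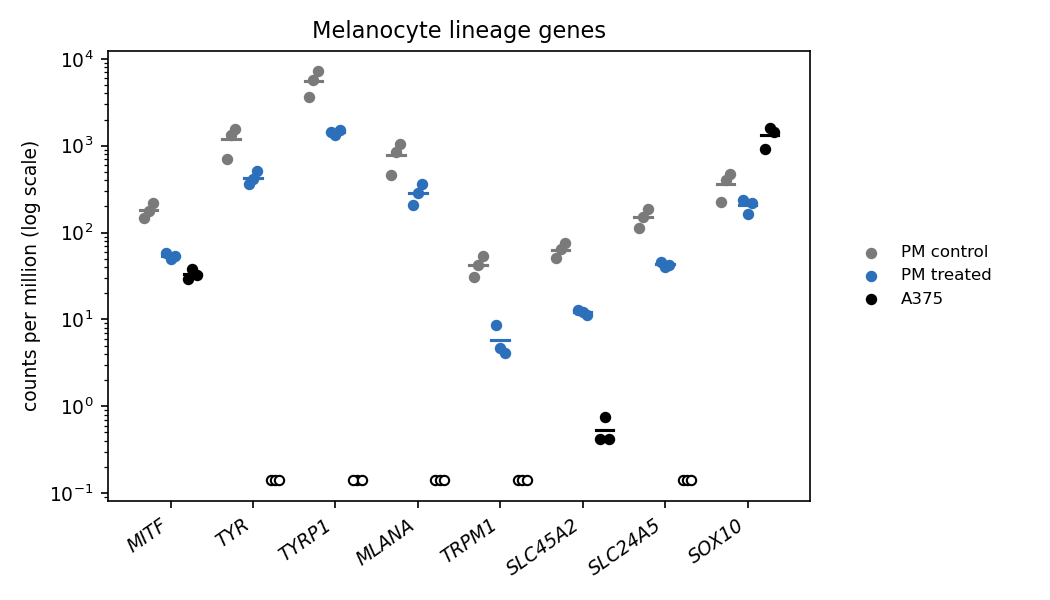
Levels of 8 melanocyte lineage genes in CPM on a log axis in PM control, PM treated and A375; each dot is 1 library, bars are means of 3 libraries, and open dots are libraries under 0.14 CPM drawn at that level. MITF averaged 181.5 CPM in PM control, 53.8 in PM treated and 33.4 in A375, whereas SOX10 averaged 365.0, 205.8 and 1323 CPM.

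Of 16 NRF2 and oxidative stress genes, 8 rose in melanocytes and 8 did not pass (13 adjusted over the list alone), with the ferritin gene FTH1 at +2.13 ± 0.24, GCLM, for glutathione synthesis, at +1.5 ± 0.20 and SRXN1 at +1.02 ± 0.15 (adjusted p = 9.60e-09, and adjusted p = 0.386 with an estimated correlation). SRXN1 did not pass without PM_control replicate 2 (0.0539). Without PM_treated replicate 1, 13 of the 16 rose. Of 20 hypoxia and glycolysis genes, 7 rose and 13 did not pass (11 adjusted over the list alone), among them the angiogenic factor gene VEGFA (+1.64 ± 0.15) and PFKFB4 (+1.09 ± 0.15). This list passed upward (adjusted p = 7.66e-06, and adjusted p = 0.386 with an estimated correlation). With the A375 share subtracted 3 of the 20 rose and PFKFB4 did not pass (adjusted p = 0.0968). Of 16 genes of endoplasmic reticulum chaperones, 6 rose and 10 did not pass (8 adjusted over the list alone), with PDIA4 at +0.72 ± 0.10 (adjusted p = 0.000517, and adjusted p = 0.386 with an estimated correlation). Of 17 p53 targets and cell cycle inhibitors, 7 fell and 10 did not pass (8 adjusted over the list alone), with the p53 target genes TP53INP1 at -1.11 ± 0.22 and TP53I3 at -0.74 ± 0.12 (adjusted p = 0.00258, and adjusted p = 0.511 with an estimated correlation). TP53INP1 and TP53I3 did not pass without PM_control replicate 2 (0.0881 and 0.0608) or PM_treated replicate 2 (0.0907 and 0.0614), nor TP53INP1 without PM_control replicate 3 (0.0754) or PM_treated replicate 3 (0.0613).

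In the TGF-beta and myofibroblast list, 8 of 18 members rose, 3 fell (TAGLN at -1.86, MYL9 at -1.15 and ACTA2) and 7 did not pass in melanocytes (14 adjusted over the list alone). The matrix genes TNC (+1.67 ± 0.17) and TGFBI (+1.26 ± 0.15) and the TGF-beta target PMEPA1 (+1.36 ± 0.11) rose. The list passed upward (adjusted p = 0.00262, and adjusted p = 0.386 with an estimated correlation) but not with the replicate block (0.0701), and PMEPA1 did not pass with the A375 share subtracted (0.0584). Of 20 genes of the invasive or dedifferentiated melanoma state, 6 rose, 3 fell and 11 did not pass (10 adjusted over the list alone). TWIST1 (+1.25 ± 0.16) and NGFR (+0.88 ± 0.09) rose and the epithelial cadherin gene CDH1 (-3.73), SOX9 (-1.70 ± 0.21) and VIM (-0.53) fell. Members have no set direction, so a fall need not oppose that state. The list passed upward (adjusted p = 0.0328, and adjusted p = 0.386 with an estimated correlation), but not with the replicate block (0.0993) nor without PM_treated replicate 2 (0.0621) or 3 (0.0655). The ATF4 amino acid response list, with 6 rises, 2 falls and 13 members not passing of 21 (14 adjusted over the list alone), passed upward (adjusted p = 0.00687, and adjusted p = 0.656 with an estimated correlation). CEBPB led it (+1.51 ± 0.14), against falls of the amino acid transporter genes SLC7A5 (-0.88 ± 0.12) and SLC3A2 (-0.41). It did not pass with the replicate block (0.0503), without PM_control replicate 1 (0.0575) or without PM_treated replicate 3 (0.0633). NGFR (0.351) and SLC7A5 (0.279) did not pass in the fit of all 15 libraries.

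Cholesterol synthesis genes (6 rose and 14 did not pass of 20, with 7 adjusted over the list alone) passed upward in melanocytes (adjusted p = 0.00687, and adjusted p = 0.656 with an estimated correlation) but not without PM_treated replicate 1 (0.184), where 1 of the 20 rose. Examples were DHCR7 (+0.81 ± 0.14) and INSIG1 (+0.68 ± 0.16), and neither passed without PM_control replicate 2 (0.0782 and 0.136), PM_control replicate 3 (0.0506 and 0.122) or PM_treated replicate 2 (0.0683 and 0.116), nor INSIG1 without PM_treated replicate 1 (0.0541). In the fit of all 15 libraries they were at 0.0945 and 0.335. Ribosomal protein genes passed upward (adjusted p = 0.0075, and adjusted p = 0.791 with an estimated correlation) with 1 of 29, RPL27 (+0.48 ± 0.12), rising and 28 not passing (0 adjusted over the list alone). The ribosomal list did not pass without PM_treated replicate 1 (0.121) or PM_control replicate 3 (0.131), and RPL27 passed in 1 of 6 fits with a library left out (up to 0.16). Mitochondrially encoded mRNAs passed downward as a list (adjusted p = 0.0241, and adjusted p = 0.683 with an estimated correlation), with a median of -0.27. None (0) of the 13 passed on its own with edgeR or adjusted over the list alone, 3 had an unadjusted p under 0.05 and DESeq2 called 5. The list did not pass with the A375 share subtracted (0.0799) nor without PM_control replicate 1 (0.118) or PM_treated replicate 3 (0.119). Interferon-stimulated genes had a median of -1.68 and passed downward as a list (adjusted p = 4.76e-05, and adjusted p = 0.656 with an estimated correlation). However, 0 of 23 passed singly with edgeR, 17 had an unadjusted p under 0.05, 14 passed adjusted over the list alone and DESeq2 called 10. IFI6, the most abundant member, had -0.96 ± 0.50 (adjusted p = 0.236). Without replicate 1 in both groups all 23 fell, with a median of -2.23, and IFI6 passed there (0.00278) and without PM_control replicate 1 (0.0067). With the replicate block or the A375 share subtracted 0 of 23 passed singly, and without PM_treated replicate 1 only 1 did. The medians in these fits were still negative, at -1.47, -1.62 and -1.79.

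Of the fibroblast matrix genes in melanocytes, 4 of 21 rose, 3 fell and 14 did not pass (9 adjusted over the list alone). The matrix list did not pass (adjusted p = 0.649), with a median of -0.26, a mean of +0.25 and a test direction upward. The small proteoglycan gene DCN rose from 85.1 ± 24.7 to 988.2 ± 305 CPM (+3.61 ± 0.34, adjusted p = 0.00338). PDGFRA, a growth factor receptor gene of mesenchymal cells, rose by +2.43 ± 0.38 and fibronectin, FN1, by +1.24 ± 0.22. FN1 went from 2.33% to 2.83% of all counts in controls to 4.52% to 6.75% in treated libraries. DCN lies on chromosome 12 from 91140484 to 91183123 (- strand). PDGFRA did not pass without PM_control replicate 2 (0.0572) or PM_treated replicate 2 (0.0521), and FN1 did not pass without PM_control replicate 2 (0.0879) or 3 (0.0633) or PM_treated replicate 2 (0.0749) or 3 (0.0609).

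In melanocytes edgeR called 2344 of 15671 tested genes, 1009 higher and 1335 lower, of which 1008 changed at least 2-fold, and 37.1% of tested genes had all treated libraries on one side of all controls, where chance gives 10%. Of 25 lists 13 passed, 9 upward and 4 downward, none (0) held with an estimated correlation, where 2 had an unadjusted p under 0.05, and fry called 10. With the replicate block 3816 genes were called, and without replicate 1 in both groups 6548. The count without single libraries was 4037 (PM_control 1), 417 (PM_control 2), 630 (PM_control 3), 450 (PM_treated 2) and 824 (PM_treated 3). Without PM_treated replicate 1 it was 2553, of which 1873 were shared, and 471 calls were lost.

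**Figure D3:**
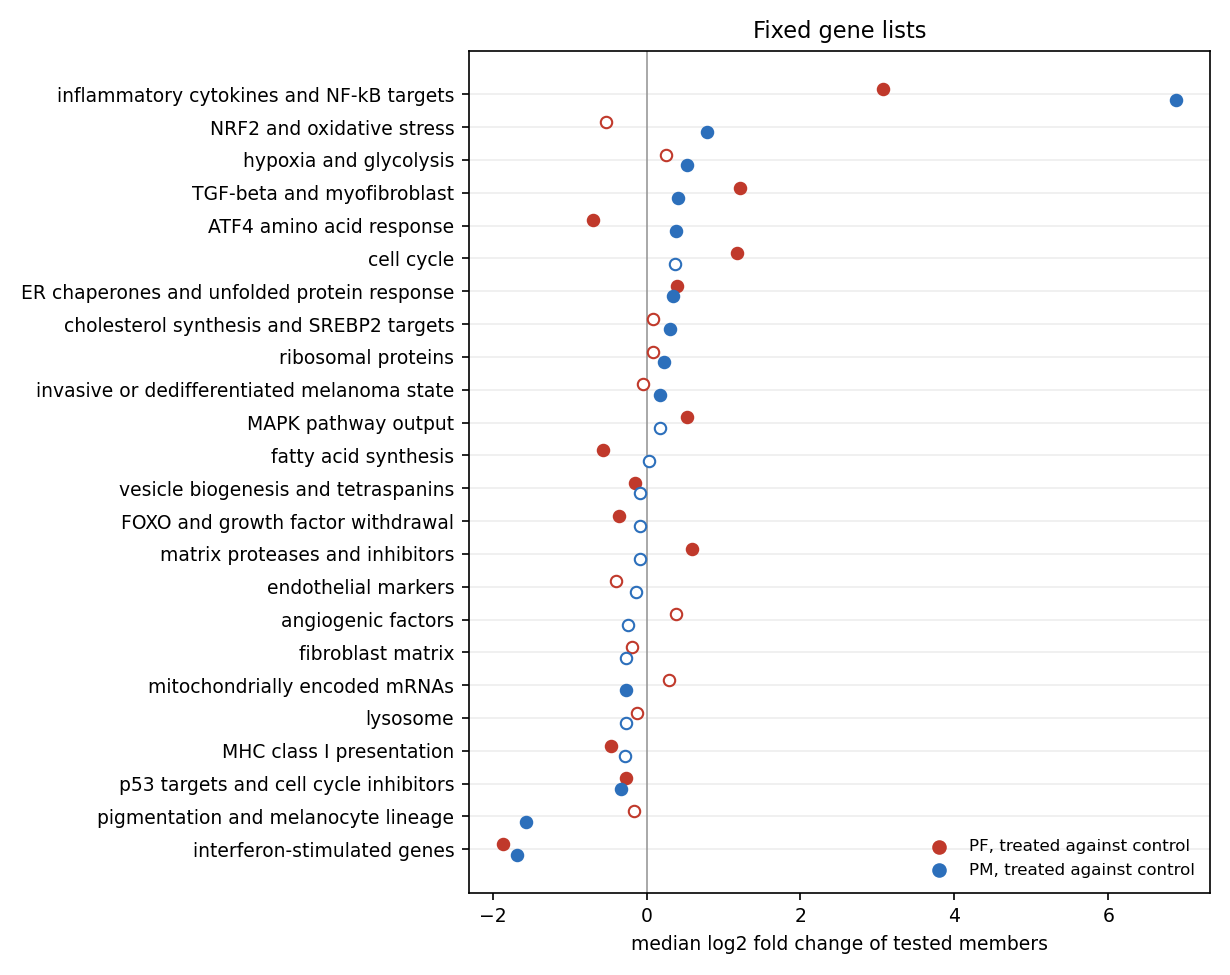
Median log2 fold change of the tested members of 24 gene lists in fibroblasts (PF) and melanocytes (PM), treated against control; filled dots are lists that passed camera with its preset correlation and open dots did not. The inflammatory list had medians of +3.07 in PF and +6.88 in PM, the interferon list -1.87 and -1.68, and the pigmentation list -0.16 and -1.56.

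Whether the effect differed between the cell types was tested directly, as the melanocyte log2 fold change minus the fibroblast one. Of 21 inflammatory genes, 12 had a larger log2 change in melanocytes. The differences were +6.40 ± 1.13 for CXCL8 (adjusted p = 0.00616), +4.27 ± 0.79 for IL6 (adjusted p = 0.00804), +4.25 ± 0.60 for SOD2 (adjusted p = 0.00189), and +2.86 ± 0.38 for NFKBIA, the inhibitor of NF-kB (adjusted p = 0.00124). The protease gene MMP1 differed by +6.43 ± 0.90 (adjusted p = 0.00188). LTBP2 and MMP2 went the other way, at -3.57 ± 0.18 for LTBP2 (adjusted p = 4.43e-06) and -2.81 ± 0.24 for MMP2 (adjusted p = 0.000125). LTBP2 stood at 109.3 ± 3.63 and 964.3 ± 189 CPM in control and treated fibroblasts and at 474.3 ± 32.5 and 337.9 ± 23.8 CPM in melanocytes. The difference was not past the threshold for MITF (+0.01 ± 0.17, adjusted p = 0.995), MKI67 (-0.69 ± 0.71, adjusted p = 0.605), COL1A1 (-0.39 ± 0.84, adjusted p = 0.83) or ACTA2 (+0.05 ± 0.22, adjusted p = 0.934). COL1A1 was at -1.60 without PM_treated replicate 1 and passed at -1.10 without replicate 1 in all 4 groups (4.61e-05). Of 176 genes named for either cell type, 50 differed by this test.

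In the inflammatory list 9 of 21 members did not pass (15 passed adjusted over the list alone), with a median difference of +3.15 (adjusted p = 3.00e-13, and adjusted p = 0.31 with an estimated correlation). Of 16 NRF2 genes 7 were more positive in melanocytes and 9 did not pass (12 adjusted over the list alone), with a median of +1.20 (adjusted p = 5.50e-10, and adjusted p = 0.234 with an estimated correlation). Examples were SLC7A11 (+3.67 ± 0.55), the thioredoxin reductase gene TXNRD1 (+2.15 ± 0.37) and the quinone reductase gene NQO1 (+1.55 ± 0.24). Of 21 ATF4 response genes 5 were more positive, 1 more negative (VLDLR, -2.82) and 15 did not pass (13 adjusted over the list alone), with TRIB3 at +2.79 ± 0.47 and the folate enzyme gene MTHFD2 at +2.08 ± 0.34 (adjusted p = 7.60e-06, and adjusted p = 0.505 with an estimated correlation). FOXO genes (5 more positive and 11 not passing of 16, 7 adjusted over the list alone, BCL6 at +2.23 ± 0.30 and TXNIP at +1.45 ± 0.15) had adjusted p = 0.00883, and adjusted p = 0.514 with an estimated correlation. Fatty acid synthesis (1 more positive, ME1 at +2.31 ± 0.43, and 11 not passing of 12, 2 adjusted over the list alone) had adjusted p = 0.0253, and adjusted p = 0.647 with an estimated correlation.

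Other lists were more negative in melanocytes. In the pigmentation list 3 of 19 were, with EDNRB at -3.04 ± 0.54, RAB27A at -1.65 ± 0.24 and SOX10 at -6.57 (4 adjusted over the list alone). The difference was positive in 7 of the 19, only 7 were abundant enough to be tested in fibroblasts, SOX10 had no count in PF_control, and its call was lost with the replicate block (0.0789) and with the A375 share subtracted (0.0532). It was lost too without PF_control replicate 1 (0.0615) or PF_treated replicate 2 (0.0532) or 3 (0.0659). Its median was -0.90 (adjusted p = 0.0246, and adjusted p = 0.647 with an estimated correlation). In the TGF-beta list 4 of 18 were more negative and 1 more positive (6 adjusted over the list alone), with LTBP2 against TGFB2 at +2.64 ± 0.34. That list had a median of -0.18 (adjusted p = 0.0027, and adjusted p = 0.308 with an estimated correlation). Matrix proteases (4 of 17 more negative, 2 more positive, 10 adjusted over the list alone) passed downward (adjusted p = 0.0232, and adjusted p = 0.505 with an estimated correlation). Their median of -0.21 and mean of +0.54 differ in sign, with MMP2, the cathepsin gene CTSK (-1.61 ± 0.22) and PLAU (-3.71 ± 0.53) on one side and MMP1 on the other. No (0) cell cycle gene passed singly with edgeR (0 adjusted over the list alone, 4 of 25 at an unadjusted p under 0.05, 2 by DESeq2). The cell cycle list had a median of -0.81 (adjusted p = 0.00181, and adjusted p = 0.647 with an estimated correlation). Mitochondrially encoded mRNAs (0 of 13 singly with edgeR, 10 at an unadjusted p under 0.05, 6 by DESeq2, 7 adjusted over the list alone) had a median of -0.59 (adjusted p = 0.000194, and adjusted p = 0.505 with an estimated correlation).

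In this comparison edgeR called 1410 of 16645 genes, 742 more positive in melanocytes and 668 more negative, and DESeq2 called 2240. Of 25 lists 10 passed, 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry called 2. Without replicate 1 in all 4 groups 5040 genes were called, and without PF_treated 2 or 3, PM_control 2 or 3, or PM_treated 2 or 3 the count was 922, 872, 741, 795, 809 and 855. Across 14353 genes tested in both cell types, which are not independent replicates, the log2 fold changes had a Pearson r of 0.45 and a Spearman rho of 0.40, and r was 0.19 with no filter on low counts. Of these genes, 355 rose in both, where independent lists would share 121.8, 436 fell in both (142.1), and 111 were called in opposite directions (264.7). The comparisons share no library.

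The cells that conditioned the medium were compared with untreated melanocytes to describe the source of the treatment. PRAME, a tumour antigen gene on chromosome 22 from 22547701 to 22559361 (- strand), stood at 219.5 ± 68.3 CPM in A375 and had no count in melanocytes, at least 1565-fold higher. HAPLN1, a hyaluronan link protein gene, was at least 2532-fold, FDCSP at least 1604-fold, the siderophore-binding lipocalin gene LCN2 at least 1269-fold, and the tumour antigen genes XAGE1B and MAGEA3 at least 1132-fold and 866.9-fold higher. The pigment genes TYR and MLANA and the non-coding RNA MEG3 had no count in A375 and were at least 8645-fold, 5605-fold and 11060-fold lower. TYRP1 (ratio 118300, 95% counting interval 40480 to 573600), COL1A2 (124800, 34540 to 1030000) and GREM1, a bone morphogenetic protein antagonist gene (46950, 8426 to 1854000), had 1 to 3 counts in A375. SOX10 (+1.70 ± 0.31), MKI67 (+2.89 ± 0.47) and CXCL8 (+9.07 ± 0.26) were higher and MITF (-2.60 ± 0.18), COL1A1 (-8.01 ± 0.69), IL6 (-5.05 ± 0.49) and ACTA2 (-1.54 ± 0.45, adjusted p = 0.0185) lower in A375. MMP1 was lower (-1.77 ± 0.54, adjusted p = 0.0235), a call lost without A375 replicate 2 (0.0732) or 3 (0.0703) or PM_control replicate 1 (0.0624), 2 (0.0555) or 3 (0.0568). It was at -2.66 without replicate 1 in both groups.

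Of 18 tested cancer-testis antigen genes, 17 were higher and 1 lower in A375 (18 adjusted over the list alone), with a median of +12.29, or +9.59 with the 12 genes at 0 in melanocytes set to their bound (adjusted p = 1.97e-36, and adjusted p = 0.00596 with an estimated correlation). All 25 cell cycle genes were higher (median +2.47, adjusted p = 2.29e-08, and adjusted p = 0.451 with an estimated correlation). So were 12 of 17 inflammatory genes, against 2 lower (median +3.14, adjusted p = 2.39e-06, and adjusted p = 0.238 with an estimated correlation) and 22 of 29 ribosomal protein genes (median +0.77, adjusted p = 0.00271, and adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone 25, 12 and 23 members were higher. Pigmentation genes (17 of 19 lower and 1 higher, SLC45A2 at -7.05 ± 0.28), fibroblast matrix genes (17 of 21 lower and 2 higher, FN1 at -9.51 ± 0.34), interferon-stimulated genes (22 of 23) and p53 targets (13 of 17, ZMAT3 at -3.16 ± 0.15) were lower. In that order these lists had adjusted p of 6.04e-24, 1.54e-12, 2.67e-05 and 3.28e-06, and adjusted p of 0.214, 0.2, 0.543 and 0.238 with an estimated correlation. Adjusted over the list alone 17, 17, 23 and 14 of their members were lower. In all, edgeR called 10727 of 16771 genes, 5483 higher and 5244 lower in A375, and 19 of 27 lists passed, 4 higher and 15 lower, 1 of them, the cancer-testis antigens, with an estimated correlation. MAGEA3, XAGE1B and others of these antigen genes have near-identical copies, and how the counting treated shared reads is not given in the sources used here, so their single values are uncertain.

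The other lists that passed were lower in A375. Of matrix proteases 12 of 16 were lower and 2 higher, PLAU at -11.45 ± 0.37 (14 adjusted over the list alone, adjusted p = 4.14e-06, and 0.173 with an estimated correlation). Cholesterol synthesis had 16 of 20 lower, LSS at -2.89 ± 0.13 (16 adjusted over the list alone, adjusted p = 2.55e-05, and 0.451 with an estimated correlation). Among lysosomal genes 14 of 18 were lower and 1 higher, CTSD at -2.90 ± 0.19 (15 adjusted over the list alone, adjusted p = 0.00271, and 0.477 with an estimated correlation). MHC class I presentation had 13 of 17 lower, ERAP2 at -4.86 ± 0.18 (13 adjusted over the list alone, adjusted p = 0.00384, and 0.55 with an estimated correlation). Angiogenic factors had 10 of 15 lower, THBS2 at -5.84 ± 0.34 (10 adjusted over the list alone, adjusted p = 0.00404, and 0.2 with an estimated correlation). Vesicle genes had 12 of 16 lower, CD81 at -2.60 ± 0.18 (12 adjusted over the list alone, adjusted p = 0.00527, and 0.238 with an estimated correlation). FOXO genes had 8 of 16 lower and 1 higher, CITED2 at -3.73 ± 0.25 (9 adjusted over the list alone, adjusted p = 0.0114, and 0.55 with an estimated correlation). Of mitochondrially encoded mRNAs 9 of 13 were lower, MT-ND5 at -1.5 ± 0.17 (9 adjusted over the list alone, adjusted p = 0.0309, and 0.55 with an estimated correlation). Fatty acid synthesis had 9 of 12 lower, FADS2 at -4.71 ± 0.28 (9 adjusted over the list alone, adjusted p = 0.0332, and 0.477 with an estimated correlation). The TGF-beta list had 9 of 18 lower and 4 higher, LTBP2 at -6.76 ± 0.18 (13 adjusted over the list alone, adjusted p = 0.037, and 0.385 with an estimated correlation). In the invasive state list 10 of 20 were lower and 4 higher, SNAI2 at -5.72 ± 0.41 (14 adjusted over the list alone, adjusted p = 0.0455, and 0.238 with an estimated correlation).

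Treated cells were then set against the A375 profile. Over 17820 genes the Pearson correlation of each library with the mean A375 profile was 0.720 ± 0.008 in PF_control and 0.749 ± 0.007 in PF_treated (difference +0.030). In melanocytes it was 0.765 ± 0.008 in PM_control and 0.807 ± 0.037 in PM_treated (difference +0.042; n = 3 per group). Over genes of at least 10 CPM the differences were +0.050 in PF and +0.079 in PM. All treated libraries lay above all controls in both cell types, and the two-sided exact permutation p was 0.1 in each, the smallest that 3 against 3 libraries can give. With sign flips within the 3 possible pairs of equal number, tried after their correlations were seen, the exact p was 0.25 in each, the smallest that 3 pairs can give. Among the melanocytes the value was 0.849 in PM_treated replicate 1 and 0.788 and 0.782 in replicates 2 and 3, against 0.760 to 0.775 in controls, and the difference without PM_treated replicate 1 was +0.020.

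Transcripts restricted to A375, with at least 20 CPM in each A375 library and under 0.5 CPM in each control library of the cell type, were counted in the treated cells. Over 114 such genes in fibroblasts the median level in PF_treated minus PF_control was 0.0198% of the A375 level, and the single libraries stood at 0.0158%, 0.0319% and 0.0357%. Over 79 such genes in melanocytes it was 4.0%, made up of 11.7%, 0.183% and 0.348% in PM_treated replicates 1, 2 and 3. The median was 0 in each control library. Genes low in both controls and A375 averaged 0.0119 and 0.013 CPM in control and treated fibroblasts and 0.0128 and 0.0235 CPM in control and treated melanocytes.

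**Figure D4:**
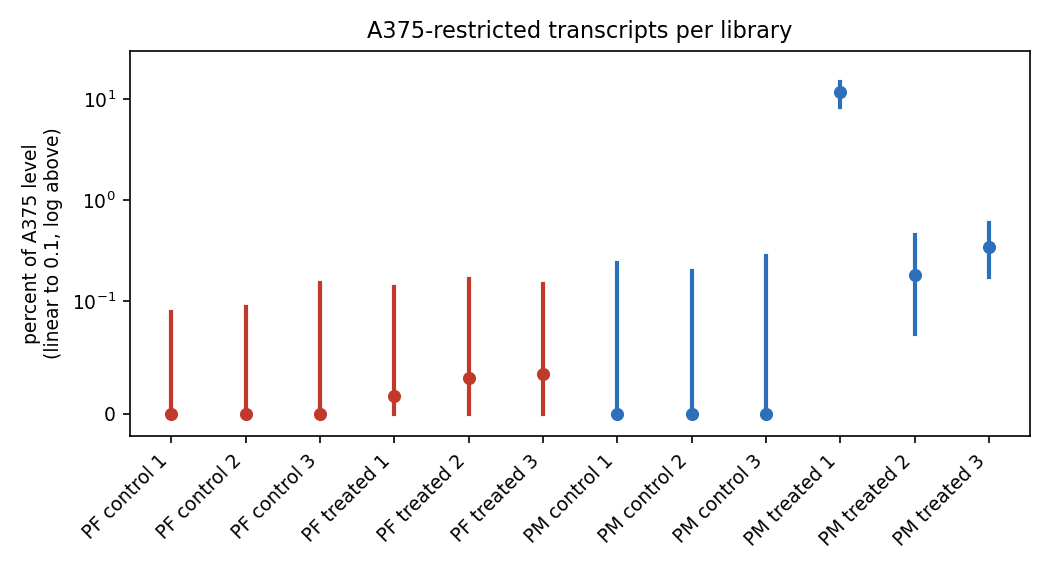
Level of transcripts restricted to A375 in each treated and control library, as percent of the A375 level on an axis that is linear up to 0.1 and logarithmic above; dots are medians over 114 genes in fibroblasts (PF) and 79 genes in melanocytes (PM), and bars run from the lower to the upper quartile of the genes. PM treated 1 stands at 11.7%, and every other library is at or below 0.348%.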

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

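Of the tests in this part, those of uptake common to the treatment, of fibroblasts in the melanocyte cultures and of A375 transcripts as the source of the cytokine rise were chosen only after the result was seen. The results here drew a closer look because the effect of treatment differed between the cell types by a test of the difference itself, which called 1410 genes. As differences of log2 fold changes (PM minus PF), the largest among genes of at least 10 CPM in a group were +10.20 for HSD11B1, +9.90 for MMP3, +7.87 for H19, +7.65 for AQP3, +7.37 for G0S2 and +7.20 for SERPINA3 on one side. On the other side were -9.02 for BCL2A1, -6.88 for MMP8, -6.57 for SOX10, -6.18 for LRRC15, -5.36 for P4HA3 and -5.14 for GABBR2. Several of these rest on near-absent levels and their fitted values depend on the prior count. SOX10 stood at 0 and 0.294 CPM and BCL2A1 at 0 and 2.01 CPM in control and treated fibroblasts, MMP8 at 0.0152 CPM (1 count) in control fibroblasts, and MMP3 and HSD11B1 at 0 and 0.0157 CPM (1 count) in control melanocytes. SERPINA3 was at +3.75 without PM_treated replicate 1, +3.37 without replicate 1 of every group and -4.63 with the A375 share subtracted. AQP3 was at +5.16 without PM_treated replicate 1, +3.33 without replicate 1 of every group and +6.04 with the share subtracted. Over the alternatives, adjusted p ranged up to 0.0621 for HSD11B1, 0.2255 for MMP3, 0.1709 for AQP3, 0.1455 for G0S2, 0.2823 for SERPINA3 and 0.0789 for SOX10 (the last with the replicate block), and those of H19, BCL2A1, MMP8, LRRC15, P4HA3 and GABBR2 stayed at or below 0.00602.

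Inflammatory and protease genes differed by +4.27 (IL6), +6.40 (CXCL8), +6.43 (MMP1), +2.86 (NFKBIA) and +4.25 (SOD2), stress and metabolic genes by +2.31 (ME1), +3.67 (SLC7A11), +2.08 (MTHFD2), +1.45 (TXNIP), +2.23 (BCL6) and +1.55 (NQO1), and TGFB2 by +2.64. More negative in PM were RAB27A (-1.65), EDNRB (-3.04), LTBP2 (-3.57), MMP2 (-2.81) and CTSK (-1.61). Passing lists (0 with estimated correlation) had medians of -0.90 (pigmentation), -0.18 (TGF-beta), -0.21 (proteases, mean +0.54), +3.15 (inflammatory) and -0.81 (cell cycle). Next were +0.54 (fatty acids), +0.77 (ATF4), +0.37 (FOXO), +1.20 (NRF2) and -0.59 (mitochondrial mRNAs).

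For the difference, 3 of 100 regroupings within cell types gave at least 1410 genes, the real one included, and the highest other gave 3242. Both others as large kept the fibroblast groups whole and mixed the melanocyte groups. The 10 regroupings of that kind, each of which still holds the whole fibroblast contrast, gave 174 to 3242 genes. Among regroupings that mixed the fibroblast groups the highest count was 111, and 0 were as large. The share is low, but it does not test whether the 2 effects are equal.

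Within each cell type 6 libraries make 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many genes in PF (3871, highest other 0), PM (2344, highest other 0) and A375 against PM_control (10727, highest other 0), with edgeR. At an unadjusted p under 0.05 the real counts were 5959, 5051 and 11350 and the highest others 630, 2472 and 247, and DESeq2 was run on the real split alone. For lists again 1 split gave as many as the real 13 in PF and in PM, and the highest others gave 11 and 12, or 6 and 12 among splits that part as many same-number pairs. Every other split has libraries of both groups on each side, so part of the treatment contrast remains in it.

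The first pattern weighed is A375 transcripts in treated melanocytes. In PM_treated replicate 1, 139 genes at least 10-fold higher in A375 but outside the restricted set exceeded the other treated libraries by a median of 10.57% of their A375 level, near the 11.65% share from restricted genes. A375 cells or RNA mixed into that culture or library are a candidate explanation. Uptake or induction common to the treatment is argued against as the whole cause, since the share was 46.46 times the highest in the other treated melanocyte libraries. The low level left in replicates 2 and 3, 0.183% over 79 genes, was matched by transcripts restricted to treated fibroblasts, at 0.1977% over 23 genes, so reads misassigned between libraries may explain it. Against misassignment at 1 rate in all libraries, A375-restricted transcripts reached only 0.0198% in treated fibroblasts, so the rate would have to differ between libraries, which was not tested. Transfer of A375 RNA by the treatment at or below that level, and induction of these genes by it, remain open.

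The second pattern is the rise of decorin in treated melanocytes, by 66.97% of the level in control fibroblasts. Fibroblasts in those cultures would bring their other abundant transcripts, but these had a median rise of -2.583% of the fibroblast level, with COL3A1 at 0.0502% and COL6A3 at 0.0561%, which argues against them. FN1 rose by 147.4%, more than fibroblasts hold. A response of the melanocytes to treatment or medium may therefore underlie the rise, as a hypothesis found and tested on the same data.

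The third pattern is the rise of inflammatory genes in both cell types. A375 transcripts carried into the libraries would account for a median of 0.5289% of the rise over called members in melanocytes and 0% in fibroblasts. In PM_treated replicate 1 alone they would account for 4.597%. This argues against them as the cause for the list as a whole, but a median does not speak for each member. IL1A averaged 3 CPM in PM_treated and 94.48 CPM in A375, so its rise may come from such transcripts. A change from growth medium to serum-free DMEM cannot be told apart from conditioning by A375, since 0 libraries came from cells in unconditioned medium. The shared response may thus reflect either.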

How the results depend on the processing

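Leaving out replicate 1 of every group and subtracting the A375 share were chosen only after the data were seen, as were the values of restricted transcripts without single libraries and the sign flips within pairs for similarity. Of the named results under all alternatives, 5103 kept their direction and side of the threshold, 448 lost their call, 22 gained one and 1 reversed: SERPINA3 in the difference, at -4.63 (adjusted p = 0.282, range over its alternatives 0.000207 to 0.2823) with the A375 share subtracted, against +7.20, since A375 holds 1561 CPM of it. Counts of called genes moved most with the libraries used. Leaving out single libraries gave 1818 to 5189 genes in PF, 417 to 4037 in PM and 741 to 1731 for the difference, and leaving out replicate 1 throughout gave 7759, 6548 and 5040, with 3844 of 3871 PF calls and 2333 of 2344 PM calls shared. With the replicate block PM gave 3816, and beyond the calls given with their results the block changed those of MCOLN1 in PF and TYMS, ME1, FGF2 and KRT17 in PM and no other named gene or list in PF or PM, SOX10 and BTG2 in the difference aside. DESeq2 gave 2240 for the difference. A fold of at least 2 left 1739, 1008 and 901 by construction. An estimated correlation left 0 lists in PF and 0 in PM with camera, with 3 and 2 at an unadjusted p under 0.05 and 13 and 10 by fry. The correlation of effects (0.45) was 0.19 with no low-count filter, 0.45 with the block, 0.48 over genes of at least 10 CPM, 0.43 without replicate 1 and 0.42 to 0.45 without single libraries. Similarity to A375 differed by 0.050 in PF and 0.079 in PM over genes of at least 10 CPM. A375-restricted transcripts in PF were 0.0222% at 100 CPM or more in A375, 0.0181% with 0 counts in controls, and 0.0150% to 0.0206% without single libraries. Except where the construction shows it (fewer libraries or genes), the cause was not tested. Depth limits values under 0.142 CPM, and 2-fold changes were recovered in 43.3% (PF) and 56.7% (PM) of simulated cases. Those cases lacked the replicate 1 offset, possible pairs and A375 share of the real libraries.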

Other observations

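In this part no test was chosen after a result was seen beyond those named above, and members named for small counts were picked after their values were seen. In fibroblasts the fibroblast matrix list moved both ways: 4 of 22 rose (VCAN at +2.17 ± 0.12, POSTN at +2.28 ± 0.23, BGN at +0.97 ± 0.16 and DCN at +0.72), 4 fell (LOX at -1.72 ± 0.26, THY1 at -0.90, SPARC at -0.46 and LUM at -0.42) and 14 did not pass (8 adjusted over the list alone), with adjusted p = 0.721. Its median was -0.19 and its mean +0.03, and the test pointed upward. In NRF2 genes 3 of 16 rose (HMOX1 at +1.59 ± 0.22, GCLM at +1.06 ± 0.09 and FTH1 at +0.82), 6 fell, among them NQO1 (-1.29 ± 0.20), and 7 did not pass (10 adjusted over the list alone, adjusted p = 0.288). In the hypoxia list 4 of 19 rose (VEGFA at +2.54 ± 0.29, HK2 at +1.60 ± 0.36, NDRG1 at +0.86 ± 0.17 and SLC16A3 at +0.75 ± 0.12) and 15 did not pass (4 adjusted over the list alone, adjusted p = 0.0911). The list passed without PF_control replicate 1 (0.0201), without PF_treated replicate 1 (0.0443) and without replicate 1 of both groups (0.0021). Angiogenic factors (6 of 16 rose, 3 fell and 7 did not pass, 10 adjusted over the list alone, adjusted p = 0.0867) included PGF (+2.27 ± 0.33) and ANGPTL4 (+1.97 ± 0.27), and passed without PF_control replicate 1 (0.00387) or without replicate 1 of both groups (0.0053). In the fit of all 15 libraries BGN (0.162), GCLM (0.0794), NDRG1 (0.16) and SLC16A3 (0.0569) did not pass. Without PF_treated replicate 2 or 3, HK2 (0.0659 and 0.0697) and NDRG1 (0.0551 and 0.05995) did not, nor HK2 with no low-count filter (0.104).

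The remaining fibroblast lists did not pass. In the pigmentation list 1 of 7 rose (EDNRB, +1.90 ± 0.33) and 1 fell (MITF, -1.70), with 3 adjusted over the list alone and adjusted p = 0.703. In cholesterol synthesis 1 of 20 rose (NSDHL, +0.49 ± 0.15) and 2 fell, SREBF2 at -0.38 ± 0.09 among them, with 2 adjusted over the list alone, adjusted p = 0.813, a median of +0.08, a mean of -0.04 and a downward test. In the invasive state list 5 of 18 rose, WNT5A at +2.38 ± 0.16, and 5 fell, with 10 adjusted over the list alone. Its adjusted p was 0.721, its median -0.05 and its mean +0.07, tested upward. Of lysosomal genes 1 of 18 rose (NPC1, +0.97 ± 0.19) and 4 fell (5 adjusted over the list alone, adjusted p = 0.593). Endothelial markers had 2 of 7 rising (KDR at +2.94 ± 0.67 and TEK at +1.40 ± 0.41) and 1 falling (EMCN, -5.15 ± 0.67), with 3 adjusted over the list alone, adjusted p = 0.938, a median of -0.40 and an upward test. TEK did not pass with the replicate block (0.0848). Of 6 fits with a library left out, NSDHL passed in 1 (adjusted p up to 0.13, log2 change down to +0.32), SREBF2 in 2 (up to 0.0904), KDR in 2 (up to 0.0778), TEK in 1 (up to 0.147) and PERP, of the keratinocyte markers, in 1 (up to 0.111). NSDHL did not pass with DESeq2 size factors (0.0516), nor SREBF2 in the fit of all 15 libraries (0.252). No (0) mitochondrially encoded mRNA passed with edgeR (0 adjusted over the list alone, 2 of 13 at an unadjusted p under 0.05, 1 by DESeq2). That list had adjusted p = 0.108, and 0.00876 without PF_treated replicate 1 and 0.00301 without replicate 1 of both groups. No ribosomal protein gene passed either (0 of 29, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2, list adjusted p = 0.555). Of keratinocyte markers 1 of 4 fell (PERP, -0.68 ± 0.20, 2 adjusted over the list alone). Leukocyte markers had 1 of 3 rising (LAPTM5, +1.70 ± 0.24, 1 adjusted over the list alone). Both were too few for a list test, and 0 cancer-testis genes were tested.

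In melanocytes matrix proteases split, with 4 of 16 up (MMP3, MMP1, SERPINB2 at +3.16 ± 0.33 and TIMP1 at +0.72), 4 down (PLAU at -1.90 ± 0.28, TIMP3 at -1.59, CTSK at -0.94 and TIMP2 at -0.91 ± 0.14) and 8 not passing (9 adjusted over the list alone). The adjusted p was 0.649, the median -0.09 and the mean +1.37, tested upward. That list passed without PM_treated replicate 1 (3.55e-06), without replicate 1 of both groups (0.000245) and with the replicate block (0.0198). Angiogenic factors (3 of 16 rose, 5 fell and 8 did not pass, 11 adjusted over the list alone, adjusted p = 0.388) included IGFBP5 (-2.40 ± 0.19). MAPK output (4 of 18 rose, 3 fell and 11 did not pass, 8 adjusted over the list alone, adjusted p = 0.273) included IER3 (+2.63 ± 0.37). No (0) cell cycle gene of 25 passed with edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2). The cell cycle list (adjusted p = 0.233) passed with the block (0.0125), without PM_control replicate 1 (0.0161) and without PM_treated replicate 3 (0.00166). Its median of +0.37 was -0.09 without PM_treated replicate 1, the library with A375 transcripts, where 0 rose and 1 fell, and +0.06 with the A375 share subtracted. All 25 of these genes were higher in A375 than in PM_control. The lysosome list (1 of 18 rose, SQSTM1 at +1.09 ± 0.15, 3 fell, 5 adjusted over the list alone, adjusted p = 0.106) passed without PM_control replicate 1 (0.01). MHC class I presentation (1 of 17 fell, ERAP2 at -0.48 ± 0.10, 1 adjusted over the list alone, adjusted p = 0.388) passed without PM_control replicate 1 (0.00798) and without replicate 1 of both groups (0.0395). ERAP2 passed in 2 of 6 fits with a library left out (up to 0.1195) and not with the A375 share subtracted (0.0591). MMP3 passed in 2 of 6 (up to 0.0635) and not with no low-count filter (0.209). TIMP2 was lost without PM_control replicate 2 (0.0658) or PM_treated replicate 2 (0.0605), and PLAU without PM_treated replicate 2 (0.0535).

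The other melanocyte lists did not pass. Fatty acid synthesis had 2 of 12 rising and 2 falling, with SCD at -0.84 ± 0.16 (5 adjusted over the list alone, adjusted p = 0.967, median +0.03, tested downward). FOXO genes had 2 of 16 rising and 2 falling, with BCL6 at +1.29 ± 0.17 (4 adjusted over the list alone, adjusted p = 0.649). Of vesicle genes 3 of 16 fell, with FLOT1 at -0.94 ± 0.12 (5 adjusted over the list alone, adjusted p = 0.225). Keratinocyte markers had 1 of 5 rising, LAMB3 at +2.02 ± 0.41, and 2 falling (4 adjusted over the list alone, adjusted p = 0.494). Of endothelial markers 0 of 5 passed with edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2). That list had adjusted p = 0.967, a median of -0.14 and a mean of +0.03, tested upward. Of leukocyte markers 1 of 4 rose (LAPTM5, +2.58 ± 0.35, 3 adjusted over the list alone). Among cancer-testis genes 1 of 2 fell (SSX1, -1.75 ± 0.30, 2 adjusted over the list alone). Both were too few for a list test. SCD, LAMB3 and SSX1 each passed in 2 of 6 fits with a library left out (up to 0.0903, 0.0948 and 0.0642). SCD did not pass in the fit of all 15 libraries (0.168), nor LAMB3 with no low-count filter (0.121).

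Other lists did not pass for the difference between cell types. Of fibroblast matrix genes 5 of 22 were more positive in melanocytes, DCN at +2.88 ± 0.38, and 2 more negative, VCAN at -2.32 ± 0.35 and POSTN at -2.99 (9 adjusted over the list alone, adjusted p = 0.366). Fewer members passed in hypoxia (1 of 20, ALDOA at +0.55 ± 0.15, 5 adjusted over the list alone, 0.142), cholesterol synthesis (1 of 20, LSS at +1.02 ± 0.27, 0 adjusted over the list alone, 0.0862) and ER chaperones (1 of 16 each way, 4 adjusted over the list alone, 0.204). MAPK output (1 of 18 more positive and 2 more negative, DUSP4 at -2.56 ± 0.52, 5 adjusted over the list alone, 0.0885) and p53 targets (2 of 17, BTG2 at +1.62 ± 0.43, 2 adjusted over the list alone, 0.566) did not pass either, nor did BTG2 itself with the replicate block (0.0855). The same held for the invasive state (1 of 20 each way, TWIST1 at +2.15 ± 0.27, 8 adjusted over the list alone, 0.0663), angiogenic factors (1 of 18 more positive and 4 more negative, HGF at -3.05 ± 0.46, 8 adjusted over the list alone, 0.142) and endothelial markers (1 of 7 more negative, KDR at -3.62 ± 0.91, 1 adjusted over the list alone, 0.405, median +0.25, tested downward). Of 12 fits with a library left out, ALDOA, LSS and KDR passed in 4 each (up to 0.106, 0.101 and 0.0763) and BTG2 in 3 (up to 0.0821, and 0.0855 with the replicate block). Without replicate 1 of every group BTG2 was at +0.77. With no low-count filter ALDOA (0.0844) and DUSP4 (0.0551) did not pass. With edgeR 0 members passed, with unadjusted and DESeq2 counts in brackets, in interferon-stimulated genes (1 and 0 of 23, adjusted p = 0.118), MHC class I presentation (3 and 0 of 17, 0.196) and vesicle genes (6 and 3 of 16, 0.177). The same was true of lysosome (6 and 1 of 18, 0.185), ribosomal proteins (0 and 0 of 29, 0.108), keratinocyte markers (2 and 2 of 6, 0.177), leukocyte markers (1 and 0 of 4, no list test) and cancer-testis genes (0 and 0 of 2, no list test). Adjusted over the list alone 2 keratinocyte markers passed and 0 members of the others.

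In A375 against untreated melanocytes the lists that did not pass moved both ways. Of ATF4 response genes 6 of 21 were higher, ASNS at +2.78 ± 0.17, and 7 lower (13 adjusted over the list alone, adjusted p = 0.904, median -0.47, tested upward). ER chaperones had 7 of 16 higher, MANF at +1.42 ± 0.11, and 3 lower (10 adjusted over the list alone, adjusted p = 0.426). Also split were hypoxia (9 of 20 higher, 5 lower, SLC16A3 at -3.72 ± 0.33, 15 adjusted over the list alone, 0.713) and MAPK output (7 of 18 higher, ETV4 at +2.66 ± 0.15, 4 lower, 11 adjusted over the list alone, 0.151). Further such lists were NRF2 (2 of 16 higher, 8 lower, FTL at -1.77 ± 0.16, 10 adjusted over the list alone, 0.0776), keratinocyte markers (3 of 6 higher, KRT14 at +8.11 ± 1.03, 2 lower, 5 adjusted over the list alone, 0.713), endothelial markers (2 of 6 higher, ESAM at +3.05 ± 0.42, 1 lower, 3 adjusted over the list alone, 0.871) and leukocyte markers (3 of 5 higher, CD74 at +8.67 ± 0.42, 2 lower, 5 adjusted over the list alone, 0.0607).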
